A study of Thermothelomyces thermophilus with 6 samples.

How the data were processed

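The series holds 6 RNA-seq libraries of Myceliophthora thermophila, 2 each from mycelium without a carbon source, on glucose and on starch. Per the labels' protocols, cultures were grown for 18 h at 45 °C in Vogel's salts containing 2% glucose, washed, and moved to the test medium. The titles give 4 h in that medium. The protocol states 2% for starch and gives no concentration for glucose in the test medium. RNA was extracted with TRIzol and cleaned on columns, and libraries followed standard Illumina protocols, per the labels. The kit, its strand setting and any date or batch are not given in the sources used here.

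The authors deposited 1 table with raw read counts and RPKM for 9110 genes in each library. The submitters' processing notes name TopHat2 2.0.8b and HTSeq 0.5.4p2, without their settings. The genome build and annotation are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart, and counts of near-identical genes are uncertain. The deposited RPKM values were checked against the deposited counts. Each RPKM equalled the count divided by the library total and by 1 gene length, and 100.0% of the implied lengths of 8989 genes were whole numbers of bases (within 0.001). RPKM therefore carried no information beyond the counts, and its only use here was the gene length (median 1541 bases). The implied length was not above the gene span in the RefSeq table for 100.0% of matched genes.

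Gene IDs were matched without regard to case to locus tags of the RefSeq assembly GCF_000226095.1 ASM22609v1, and 9087 of 9110 matched. The table gives no product descriptions, and only 6 genes have a symbol other than the locus tag: gla1, cbdA, ganA, phy1, cat1 and lcc1. What these genes encode is stated as background. All other genes are given by the ID in the deposited table, because neither source pairs them with names. Because the build behind the counts is unnamed, coordinates are not printed, and the assembly served only for symbols and for the order of genes. Lists of genes by function (starch-active enzymes, cellulases, sugar transporters, central metabolism and others) had been fixed as word patterns on annotation text before the data were examined. They had no text to act on, so no list and no set test was run.

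Depth was 17726204 to 23635336 counted reads per library. At that depth 3 reads correspond to 0.127 to 0.169 CPM by library totals, before any scaling factor. Counting intervals are exact 95% Clopper-Pearson intervals and cover counting error only, since reads carry no molecular identifiers. They are given where a gene named by the rule stated further on had at most 20 reads in one of the groups compared.

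Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr were kept (8718 tested, 392 not tested, of which 121 had no read in any library). Scaling used TMM factors, and all 6 libraries entered 1 fit without covariates (estimateDisp, robust glmQLFit, glmQLFTest). The fit had 3 residual degrees of freedom, a common biological coefficient of variation of 2.5% and a median prior of 42.5 degrees of freedom. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are scaled by the TMM factors. Because about 90% of genes passed the threshold against starvation, counts from glmTreat against an absolute log2 fold change of 1 are given beside the main ones.

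The tests were tried on simulated data. Counts were drawn for the real genes from their means, the library sizes and the fitted dispersions, with known changes in the starch against glucose comparison. Of 50 genes changed by each size, the test recovered 60% at a log2 change of 0.25, 78% at 0.5, 94% at 1 and 100% at 2 (8671 genes passed the filter). False calls made up 5.1% of all calls. The simulation drew from the model that the test assumes and changed few genes, equally often up and down. In the real comparison of starch and glucose 68.6% of tested genes were called. The share of false calls there is therefore not known from the simulation.

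Genes were named by a rule fixed before the data were examined. It took, for each comparison, the genes with a symbol, the 2 largest rises and 2 largest falls among genes without informative annotation that had at least 10 CPM in the higher group and no overlap of replicates, and the 10 genes with the highest CPM, uncorrected for length, in each medium. Genes named outside the rule are marked as such. The choices fixed beforehand also covered the alternatives: DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings and filters, each library left out, fits on 2 groups, the replicate number as a block, and the non-robust fit. Removal of the gene length trend (a loess offset per library) and the classes of no carbon or glucose against both other media were added after the data were seen. Equal-depth detection used 1 random draw without replacement per library, and positions between media used log2(CPM + 0.5). Permutations and correlations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. GC content was not checked because no genome sequence was used here.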

Results

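Messenger RNA was sequenced from the thermophilic filamentous fungus Myceliophthora thermophila (Thermothelomyces thermophilus). This fungus degrades plant polysaccharides and secretes a large set of carbohydrate-active enzymes. Mycelium grown on glucose was washed and held for 4 h without a carbon source, on glucose or on soluble starch, with 2 libraries for each medium. The table held read counts for 9110 genes, and the library totals were 21820858 and 17726204 reads for no carbon, 19591786 and 23635336 for glucose, and 22539023 and 22975353 for starch. Replicate libraries were close to each other, with Pearson's r across genes of log2(CPM + 1) at 0.9981 for no carbon, 0.9988 for glucose and 0.9988 for starch. They still differed by more than counting noise, with a chi-square per gene of 8.85, 5.05 and 2.61 in the same order. A set of 6 short, abundant gene models was chosen after the values were seen, for large replicate differences without carbon and on glucose. They carried 75.6%, 59.9% and 4.6% of the chi-square sums. Large shares without carbon and on glucose follow in part from that choice. Without these 6 models the chi-square per gene was 2.16, 2.03 and 2.49. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

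Across media, starch and glucose libraries correlated at 0.974, whereas starch and no carbon libraries correlated at 0.854 to 0.860 and glucose and no carbon libraries at 0.840 to 0.845. More genes were represented in starved mycelium than in fed mycelium at equal depth. With every library thinned to 17726204 reads, 8650 and 8636 genes had at least 10 reads without carbon, 8284 and 8291 on glucose, and 8388 and 8401 on starch. Abundance and its ranks refer to reads per gene (CPM), which are not corrected for gene length, so long genes rank higher than their number of transcripts would place them. The 100 most abundant genes took 25.18% and 26.4% of the reads without carbon, 25.49% and 25.11% on glucose, and 21.8% and 21.65% on starch. Of the 10 most abundant genes of each medium, 3 were common to all media, and these were Mycth_2314451, Mycth_2141513 and Mycth_2298136. Mycth_2314451 had 8301 ± 161 CPM on starch, 7961 ± 90.6 CPM on glucose and 5025 ± 130 CPM without carbon (mean ± SD, n = 2 for all CPM values).

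The first comparison asked which genes respond to soluble starch when mycelium without any carbon source is the reference. The strongest rise of all 8718 tested genes was that of gla1 (Mycth_72393), which encodes glucoamylase, the secreted enzyme that releases glucose from the ends of starch chains. It stood at 8.22 ± 0.945 CPM without carbon and at 2477 ± 61.8 CPM on starch, a 299-fold difference (log2 fold change 8.22, SE 0.044, adjusted p = 1.8e-63, edgeR quasi-likelihood test). Its rank by CPM moved from 6931 without carbon to 20 on starch. The phytase gene phy1 (Mycth_104551) rose 33.2-fold, from 2.49 ± 0.994 to 80.2 ± 0.635 CPM (adjusted p = 6.7e-40). Expression of cbdA (Mycth_111388), a cellobiose dehydrogenase gene, rose 4.91-fold to 87.8 ± 0.861 CPM (adjusted p = 8.7e-34). The endo-galactanase gene ganA (Mycth_43163) rose 2.34-fold to 20.3 ± 0.967 CPM (adjusted p = 2.7e-15). The catalase gene cat1 (Mycth_80916) rose 1.55-fold, from 29.5 ± 0.00558 to 45.7 ± 3.65 CPM (adjusted p = 2.7e-13). The rise of cat1 did not exceed 2-fold in the test for that size. The laccase gene lcc1 (Mycth_51627) fell by 2.05 on the log2 scale, from 1.5 ± 0.165 to 0.359 ± 0.0848 CPM (adjusted p = 1.4e-05), on only 64 reads over both starved libraries and 17 over both starch libraries. The read ratio of lcc1 was 4.21, with a 95% counting interval of 2.43 to 7.66.

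Among genes without a symbol, the largest rises with at least 10 CPM on starch were those of Mycth_2074571 and Mycth_108407. Mycth_2074571 went from 0.351 ± 0.256 to 62.9 ± 4.34 CPM. Its read ratio was 190, with a 95% counting interval of 113 to 348. The log2 fold change of 7.55 became 6.87 without no carbon replicate 1 and 8.48 without no carbon replicate 2. Mycth_108407 went from 105.4 ± 8.85 to 8820 ± 399 CPM (83.8-fold, adjusted p = 6e-07) and had the highest CPM on starch. On glucose it had 5577 CPM, 53-fold above no carbon, and starch exceeded glucose 1.58-fold. The largest falls among genes with at least 10 CPM without carbon were those of Mycth_48716 and Mycth_115957. Mycth_48716 had 584.5 ± 6.34 CPM without carbon and only 4 reads in total on starch. The read ratio between the media was 6910, with a 95% counting interval of 2700 to 25400. The log2 fold change of -12.66 became -13.57 without starch replicate 1 and -12.09 without starch replicate 2. Mycth_115957 had 1341 ± 12.6 CPM without carbon and 0.401 ± 0.0843 CPM on starch. Its 19 reads on starch gave a read ratio of 3340 (95% counting interval 2140 to 5540).

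In all, 3950 genes were higher and 3896 lower on starch than without carbon at an adjusted p under 0.05 (edgeR). When the test required a difference of more than 2-fold (glmTreat), 1773 genes were higher and 1658 lower. The median absolute log2 fold change was 0.89, against a median standard error of 0.0638. Gene length moved with this comparison. Among the shortest 10% of genes (153 to 657 bases), 41.9% were more than 2-fold lower on starch and 6.5% higher. Among the longest 10% (3131 bases and more), 7% were lower and 32% higher. The Spearman correlation of length with log2 fold change across genes was 0.32, and genes are not independent replicates. After removal of the length trend, a step chosen after seeing the data, 3366 of the genes called higher and 3372 of those called lower kept their call, and 253 and 181 were called in the opposite direction.

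The second comparison, starch against glucose, set mycelium on the polymer against mycelium on its monomer. The glucose concentration of the test medium is not given, so the amount of sugar cannot be told apart from its form. The same glucoamylase gene, gla1, was 47.9-fold higher on starch than on glucose (51.7 ± 2.63 CPM on glucose, log2 fold change 5.58, SE 0.035, adjusted p = 2.1e-60), and its fold change ranked 6 among the 8718 genes. Among the other symbol-bearing genes, cbdA, ganA and phy1 were also higher on starch. Expression of cbdA was 7.28-fold higher (12.1 ± 0.85 CPM on glucose, adjusted p = 2.4e-35), and ganA was 4.23-fold higher (4.81 ± 0.096 CPM on glucose, adjusted p = 9e-21). The difference for phy1 was 1.38-fold (57.9 ± 2.56 CPM on glucose, adjusted p = 6.3e-10) and did not exceed 2-fold in the test for that size. In contrast, cat1 was lower on starch than on glucose, where it had 119.7 ± 1.23 CPM (log2 fold change -1.39, adjusted p = 1.3e-28). A difference in lcc1 was not detectable at this depth, with 17 reads on starch against 9 on glucose, a read ratio of 1.56 (95% counting interval 0.656 to 3.96) and an adjusted p of 0.41.

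The largest rises on starch over glucose among genes without a symbol and with at least 10 CPM on starch were those of Mycth_2306267, from 0.523 ± 0.142 to 51.5 ± 2.35 CPM, and Mycth_2313229, from 1.78 ± 0.055 to 113.7 ± 0.961 CPM. Mycth_2306267 rose 99.2-fold in the fit (adjusted p = 1.7e-36), and the 95% counting interval of its read ratio was 64.8 to 165. Mycth_2313229 rose 64-fold (adjusted p = 1.8e-43). The largest falls were sought among genes with at least 10 CPM on glucose, and rarer genes with larger falls were left aside. Mycth_82772 went from 6206 ± 21 CPM on glucose to 230.5 ± 0.67 CPM on starch, and Mycth_69746 from 6386 ± 15.3 to 294.5 ± 1.79 CPM. The gene with the highest CPM on glucose, Mycth_108317 (6852 bases), had 11205 ± 727 CPM there, 630.1 ± 61.5 CPM on starch and 163.7 ± 5.09 CPM without carbon. Its log2 fold change between starch and glucose was -4.15 (adjusted p = 4.88e-05). Mycth_75296 (2203 bases) and Mycth_105482 (7431 bases), ranked 3 and 4 by CPM on starch, were 2.84-fold and 4.28-fold higher on starch than on glucose (adjusted p = 5.56e-43 and 4.09e-47).

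Most genes differed little in size between these media. The test called 3150 genes higher and 2834 lower on starch than on glucose (edgeR, adjusted p under 0.05), but only 182 higher and 274 lower by more than 2-fold. The median absolute log2 fold change was 0.31. The split of calls depended on the scaling. Calls were higher on starch in 52.6% of cases with TMM factors, 49.8% with RLE factors and 56.8% with upper quartile scaling. With library totals alone the share was 73.9%, and the median of all genes shifted by 0.205. DESeq2 called 2473 genes higher and 2640 lower, so the balance turned the other way there. Length did not move with this comparison in the way it did against starvation (Spearman's rho -0.03).

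The third comparison set glucose, the sugar of the preculture, against no carbon. The series holds no library from before the move to the test medium. A rise on glucose may thus be a fall during starvation. In all comparisons, rises and falls are differences between media. Of the genes with a symbol, phy1 rose 24-fold on glucose (log2 fold change 4.58, SE 0.109, adjusted p = 6.1e-37), gla1 rose 6.24-fold (SE 0.06 on the log2 scale, adjusted p = 1.1e-37) and cat1 rose 4.06-fold (SE 0.055, adjusted p = 1.5e-34). Expression of cbdA, ganA and lcc1 was lower on glucose than without carbon, with log2 fold changes of -0.57, -0.85 and -2.68 (adjusted p = 2.6e-07, 3.2e-07 and 2.2e-06). The read ratio of lcc1, with 9 reads on glucose, was 6.54 (95% counting interval 3.24 to 15). The falls of cbdA and ganA did not exceed 2-fold in the test for that size. Among genes without a symbol and with at least 10 CPM on glucose, the largest rises were those of Mycth_2074571, from 0.351 to 65.4 ± 1.88 CPM, and Mycth_112805, from 0.25 ± 0.173 to 37.7 ± 2.97 CPM. Their read ratios were 197 (95% counting interval 117 to 361) and 160 (87 to 335). Without no carbon replicate 1 their log2 fold changes of 7.60 and 7.29 became 6.93 and 6.65, and without no carbon replicate 2 they became 8.54 and 8.15. Removal of the length trend gave 6.50 for Mycth_112805. Mycth_115957 and Mycth_2309773 showed the largest falls among genes with at least 10 CPM without carbon. Mycth_115957 went to 1.18 ± 0.412 CPM on glucose (log2 fold change -10.17), and Mycth_2309773 went from 3117 ± 2.23 to 7.51 ± 0.271 CPM (log2 fold change -8.69, or -8.10 with the length trend removed).

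This comparison gave 3907 genes higher and 3983 lower on glucose (edgeR, adjusted p under 0.05), of which the 2-fold test kept 1895 and 1869. The same length trend was present, with Spearman's rho of 0.31 across genes. Among the shortest 10% of genes, 47.7% were more than 2-fold lower on glucose, against 7.6% among the longest 10%. Removal of the trend kept 3398 and 3499 of the calls higher and lower and turned 232 and 182 to the opposite direction. Of the 10 most abundant genes without carbon, 5 were short models (219 to 432 bases) whose replicate libraries lay far apart. Mycth_2071953, for example, had 9530 ± 2267 CPM without carbon. All 5 were called lower on starch and on glucose than without carbon (adjusted p of 0.00521 to 0.0194).

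**Figure D1:**
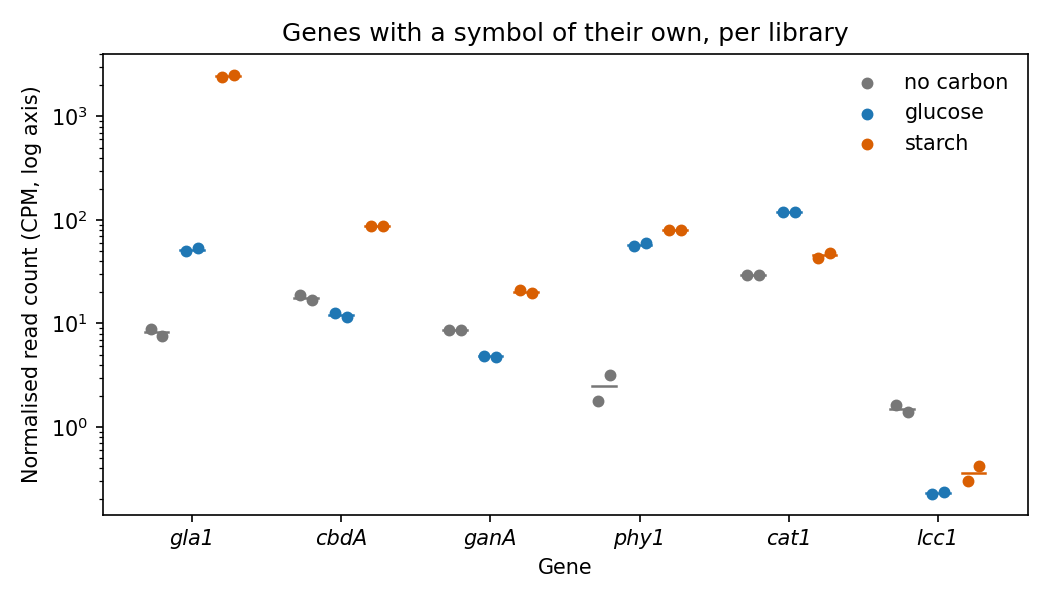
Normalised read counts (CPM, log axis) of the 6 genes that carry a symbol of their own. Points are single libraries and short bars are the means of 2 libraries per medium. The glucoamylase gene gla1 had 2477 CPM on starch against 51.7 CPM on glucose and 8.22 CPM without carbon.

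The media were next compared jointly, to find genes set apart in one medium from both others. On starch, 1572 genes were higher and 1173 lower than in both other media (adjusted p under 0.05 in both edgeR contrasts), and 82 and 58 when each difference had to exceed 2-fold. Genes gla1, cbdA and ganA belonged to the group higher on starch in both 2-fold tests. Starved mycelium was set apart most often, with 3421 genes higher and 3422 lower than in both fed media, or 1398 and 1491 by more than 2-fold. On glucose, 1877 genes were higher and 1797 lower than in both other media, or 179 and 88 by more than 2-fold. With library totals alone as the scaling, the classes of glucose held 1087 genes higher and 2894 lower at an adjusted p under 0.05, so their balance turned round, and the class lower on starch held 741. Upper quartile scaling turned the glucose balance as well, with 1651 higher and 2092 lower. Under TMM scaling, cat1 was among the genes more than 2-fold higher on glucose than in both others.

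The contrasts share libraries, so overlaps under TMM scaling were set beside reference values. In 20 simulated data sets without any effect, the overlap of calls averaged at most 0.3 genes in each class and never exceeded 3. Independent lists of the observed lengths would overlap in 1427 genes for the class higher on starch, 1266 for the class lower on starch, 1780 and 1770 for no carbon, and 1270 and 1439 for glucose, each in the order higher and lower. At the 2-fold level those values were 37, 52, 355, 385, 60 and 39. The class lower on starch thus lay below the independent-list value at the adjusted p threshold (1173 against 1266) and near it at 2-fold (58 against 52), while the other classes lay above theirs. The simulated values leave out real effects. The independent lists leave out that both contrasts of a class contain the same medium. Its true level and its libraries both favour overlap, so an excess over these lists was likely beforehand. The excess alone does not show that a medium is set apart. A split of the shared medium would leave 1 library in each part, so part of any excess may come from the shared libraries.

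Of the 182 genes more than 2-fold higher on starch than on glucose, 88 (48.4%) were also more than 2-fold higher without carbon than on glucose. Another 18 were higher on glucose than without carbon, and gla1 was one of these 18. The remaining 76 did not pass the 2-fold test between glucose and no carbon. Of the 274 genes lower on starch than on glucose, 179 (65.3%) were higher on glucose than without carbon and 11 were lower. Both comparisons contain the glucose libraries, so a gene picked for its glucose value in one is favoured in the other. In the group of 179, the glucose value exceeded both others, as for Mycth_82772 and Mycth_69746.

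For genes that separated glucose from starvation, the starch value lay close to the glucose value. Genes were picked by a 2-fold difference between glucose and no carbon in replicate 1 and measured in replicate 2. On a log2 scale from 0 (no carbon) to 1 (glucose), the median position of starch was 0.92 (quartiles 0.73 and 1.07) for 1884 genes higher on glucose, and 0.86 (quartiles 0.70 and 1.01) for 1397 genes lower on glucose. The reverse choice of replicates gave 0.92 and 0.86 as well. Starch lay nearer to glucose than to no carbon for 88.8% and 89.9% of these genes.

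**Figure D2:**
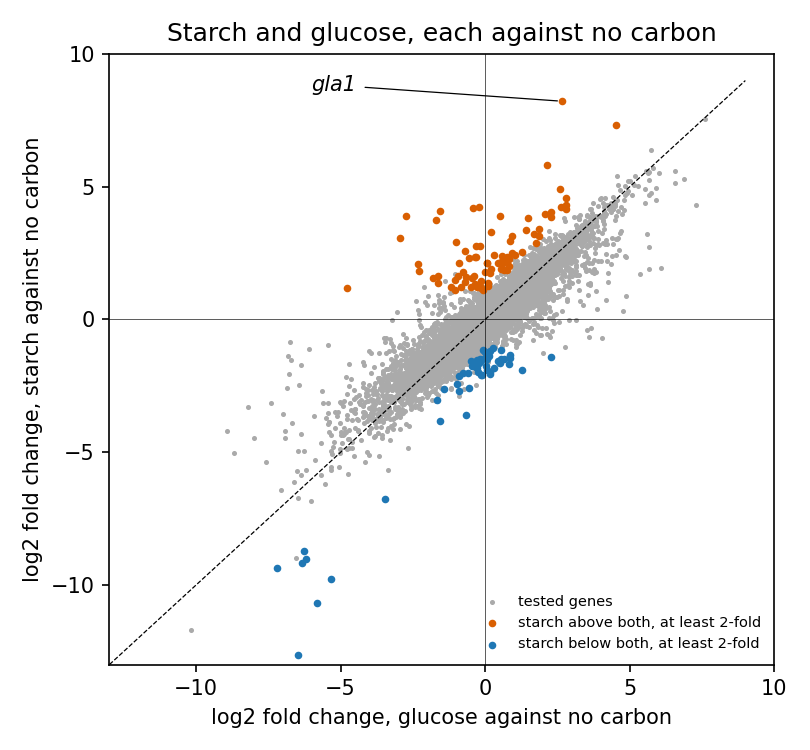
Log2 fold changes of 8718 tested genes for glucose (horizontal axis) and starch (vertical axis), each against no carbon, so both axes share the no carbon libraries. Orange points are the 82 genes more than 2-fold higher, and blue points the 58 genes more than 2-fold lower, on starch than in both other media, and the dashed line marks equal change. The highest point, gla1, lies at 2.64 and 8.22.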

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

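Of 228 values of the 12 counts of calls under 19 alternatives, 211 stayed within 1.5 times the main count. The 2-fold test gave fewer calls throughout: 1773 higher and 1658 lower for starch against no carbon, 182 and 274 for starch against glucose, 1895 and 1869 for glucose against no carbon, 82 and 58 for starch against both others, 1398 and 1491 for no carbon against both others, and 179 and 88 for glucose against both others. Its construction, a larger difference to exceed, shows the cause. Scaling by library totals alone moved 5 counts: starch against glucose to 4811 higher and 1701 lower, lower on starch than in both others to 741, and glucose against both others to 1087 higher and 2894 lower. This scaling shifted the median gene by 0.205 (starch against glucose) and -0.248 (glucose against no carbon), and upper quartile scaling shifted the latter by -0.136. With 1 library left out, genes higher on starch than glucose ranged from 2776 to 3139 and lower from 2604 to 2866. None of the 6 libraries, left out, moved a count by over 1.5 times. The library left alone in its medium was assumed to vary like those of the other media. Of 566 values for named genes, 562 kept direction and side of the threshold, although a library left out moved the size for Mycth_2074571, Mycth_112805 and Mycth_48716 by over 1.5 times. Removal of the length trend moved Mycth_112805 on glucose against no carbon from 7.29 to 6.50 and Mycth_2309773 from -8.69 to -8.10. The 4 exceptions were cat1 on starch against no carbon, phy1 on starch against glucose, and cbdA and ganA on glucose against no carbon, which did not pass the 2-fold test. With the replicate number as a block, starch against glucose gave 3182 higher and 2862 lower. No label says that a number pairs samples, and replicate differences of 7984 genes correlated between media at 0, 0.02 and 0.02. Depth limits lcc1 (at most 64 reads per medium). Set tests and other settings for gene lists were not run, since no list could be formed. Removal of the gene length trend, chosen after seeing the data, moved none of the 12 counts by over 1.5 times, but the genes behind them changed. Of the calls higher and lower, 253 and 181 turned to the opposite direction for starch against no carbon, 232 and 182 for glucose against no carbon, and 1 and 2 for starch against glucose.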

Other observations

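The tests of a shared source, of depth, of abundance, of RNA degradation and of shared reads, and the choice of the runs and short gene models, were made only after the result was seen. Genes named here were chosen after their values were seen, except where the naming rule is mentioned. Genes that changed together often lay side by side in the order of the RefSeq assembly. A run of 7 adjoining genes, from Mycth_61442 to Mycth_2311121, was more than 2-fold higher on starch than on glucose in every member, while the longest such run in 1000 shuffled gene orders was 3. It held 6 genes with over 1000 CPM on starch, among them Mycth_75296 (6324 CPM on starch, 2225 on glucose, 1406 without carbon) and Mycth_105482 (6035, 1411 and 784 CPM), both within the naming rule. The log2 fold changes of those 6 genes on starch over glucose ran from 1.45 to 2.16. The member at the end, Mycth_2311121, had few reads, with 122 on starch and 12 on glucose (read ratio 8.38, 95% counting interval 4.63 to 16.7). Against no carbon the run was mixed. Mycth_2069815 had 1306 CPM without carbon and 1163 on starch, and Mycth_2311121 had 8.24 and 2.58 CPM. The other members had more CPM on starch than without carbon.

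A second run of 8 adjoining genes was lower on starch than on glucose, from Mycth_2303701 to Mycth_48716, with at most 4 in the shuffled orders. Its members had 151 to 584 CPM without carbon. On starch, 7 of the 8 had 0.09 to 1.37 CPM, and Mycth_50920 had 42.7 CPM. All 8 genes lie within a run of 13 adjoining genes, from Mycth_2303695 to Mycth_107763, that were all more than 2-fold lower on starch than without carbon (median log2 fold change -9.01), against a longest shuffled run of 9. By median these 13 genes were also lower on glucose than without carbon (log2 fold change -5.82). Their median CPM was 380.1 without carbon, 7.33 on glucose and 0.87 on starch. Runs of 3 or more genes numbered 3 (higher) and 9 (lower) for starch against glucose, where shuffled orders gave at most 2 and 3. Against no carbon, such runs numbered 93 (higher) and 89 (lower) on starch and 104 and 113 on glucose, where shuffled orders gave at most 75, 72, 90 and 84. By length, the longest runs of the remaining comparisons did not exceed the shuffled orders: 6 genes higher on starch than without carbon (shuffled, up to 9), and 7 higher and 10 lower on glucose than without carbon (shuffled, up to 10 in both). The run of 10, from Mycth_2303695 to Mycth_2303709, lies within the run of 13 and is not a separate place.

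Across all genes, log2 fold changes of adjoining genes on starch against glucose correlated at 0.251. Reads shared between overlapping or adjoining gene models could raise this value, but such sharing should stop at the next gene. Genes 2, 3, 5 and 10 places apart correlated at 0.108, 0.071, 0.037 and -0.002. At 3 places the highest of 1000 shuffled orders was 0.032. The value at 3 places argues against shared reads as the whole cause. The drop beyond adjoining genes leaves open that shared reads gave much of the 0.251. Similar lengths of neighbours are argued against as the whole cause in the comparisons that had a length trend: after its removal the correlation of adjoining genes was 0.196 (before, 0.205) for starch against no carbon and 0.198 (before, 0.206) for glucose against no carbon. Tandem copies that share reads stay open, since no sequence was used here, and so does common regulation of neighbours, which was not tested. As a hypothesis of the same kind, a block of genes around gla1 was tested on starch against glucose. The median log2 fold change of the 10 genes that flank it was -0.03, at percentile 36.9 of 9027 windows of the same shape. A block of most of these genes was thus not found, but a median over 10 genes cannot show a smaller block. Their log2 fold changes ran from -1.14 (Mycth_2311890) to 0.97 (Mycth_2311884).

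A set of 6 short gene models (171 to 432 bases, 1988 to 4851 CPM on average) moved together between replicates, and 5 of them are among the 10 most abundant genes without carbon. In all, 11 models were under 500 bases with a mean of at least 1000 CPM. The 6 were picked from these for an absolute log2 replicate ratio over 0.4 both without carbon and on glucose. The size of their shift in those media thus restates the choice, which did not fix its direction. The median log2 ratio of replicate 1 to 2 of the 6 was -0.54 without carbon, 0.65 on glucose and 0.14 on starch. The SD over 3995 genes was 0.076, 0.066 and 0.064. Library depth or scaling is argued against, since 1 factor per library moves all genes alike: in the starch pair, which was not used to pick the 6, their median lay 0.14 from that of the 3995 genes, and the largest distance in 10000 random sets of 6 abundant genes was 0.1. Reads of one shared source, such as a single abundant RNA that covers all 6 models, may explain the pattern: the 6 fold changes between media lay closer together than in all but 0.11% of random sets of 6 abundant genes in each comparison, and the 4 members in the RefSeq table adjoin each other. They took 3.85% and 5.48% of reads without carbon but 0.83% to 1.6% in the other media, and whether that reflects the RNA content of starved cells or carry-over during library preparation stays open.

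Short genes were relatively more abundant in starved mycelium, as given with the comparisons. Lower abundance of short genes is argued against as the whole cause, because the median Spearman's rho of length and log2 fold change (starch against no carbon) was 0.24 within 10 classes of abundance and positive in 10 of 10. Loss of short fragments at size selection could contribute: rho was 0.194 among genes under 1000 bases and 0.072 (SE 0.019) among those of 2000 bases or more, which decides neither way. More degraded RNA in both starved libraries cannot be told apart from a response of short genes to starvation, because the libraries of 1 medium share it and the files hold no read positions. Replicate ratios followed length with an absolute rho of at most 0.09. After removal of the trend, 79.2% of the genes more than 2-fold higher and 75.5% of those lower on starch than without carbon were kept by the same test.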
